A study of Mus musculus with 24 samples.

How the data were processed

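The series holds 24 Illumina bead arrays of total RNA from the unsegmented caudal ends of mouse embryos (strain label C57Bl/6). Per the labels, knockout embryos carry a conditional Srf allele and a Cre driven by T, and both genotypes came from crosses of parents heterozygous for that allele. RNA was extracted with Trizol and cleaned on columns with DNase, checked on a Bioanalyser and turned into biotinylated cRNA, per the labels' protocols. The deposited non-normalized table holds the mean bead intensity of each probe on each array on a linear scale, per the file headers and its values. The same table gives a detection p-value for each probe and array, per the file headers, in steps of 1 in 798. The deposited value table holds intensity on a linear scale; its columns share 1 distribution (medians from 77.4 to 77.7, rank correlation of 1 with the non-normalized values), so quantile normalization was read from the values and is stated in no label. GenomeStudio is named per the submitters' processing notes; its version and settings are not given in the sources used here.

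Array columns were matched to samples by their titles, and no column of a sample was left unused. The non-normalized intensities were background corrected by normexp with negative control statistics inferred from the detection p, offset by 16, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.05 on at least 4 arrays were kept. For each gene symbol the probe with the highest mean over all 24 arrays was used, and probes without a symbol stood for themselves. Of 25697 probes, 23978 carry 1 symbol and 1719 none. After the filter 14927 probes gave 11008 features to test, 10135 with a symbol and 873 without. Of the symbols, 10131 were found in the reference gene table (assembly GRCm38.p6), which was used only for names and for which genes neighbour each other. Among named genes, probes of Actb differed in direction at E8.5 (0.86 against -0.27) and E9.0, and the dimmer probes of Srf, Cnn2 and Trim10 gave smaller changes at E8.75 than those used. So did other probes of Cnn2 (-0.30 against -1.03) and Wdr1 (-0.30 against -0.56) at E8.5 and of Pfkp (1.28 against 2.78), Cnn2 (-0.47 against -1.26), Ank1 (-1.22 against -2.60) and Trim10 (-2.26 against -3.26) at E9.0, where another Ank1 probe gave -2.64.

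The 6 groups (2 genotypes at 3 stages) were fitted in 1 linear model of group means over all 24 arrays with limma, so that the stages share an estimate of the spread, with moderated tests (prior degrees of freedom 5.73). The comparisons were knockout minus control at each stage, the mean of these effects, their interaction with stage by a moderated F test, and the control changes between stages. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The labels do not say whether the replicates are separate embryos or litters, so p-values measure only the spread between these samples, which may be technical. Where a probe was not above background on any of the 4 arrays of a group, its change is given as a bound ("at least"), with that group set at the lowest detected signal of its arrays; a fitted difference of effects is then not read as a size. Groups with signal on 1 of 4 arrays are given as measured, and the sizes are less certain there: Spp2 and Mrc1 in the E8.75 controls, and Kel, Ank1, Hoxd12, Foxa2, Lefty1 and Noto in the E9.0 knockouts. Fold changes are log2 unless written as N-fold.

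Of 26 gene lists fixed in advance, 25 were tested and the list of embryo sex genes served as a check of the samples. The tested lists were SRF targets of the actin cytoskeleton, immediate early SRF targets, focal adhesion with integrins and basement membrane, tail bud and primitive streak, presomitic mesoderm and segmentation clock, somite and paraxial differentiation, mesenchymal transition, epithelial, neural tube, notochord and node, gut endoderm, visceral yolk sac endoderm, primitive erythroid cells, endothelium, lateral plate and allantois, cardiomyocytes, neural crest and surface ectoderm, anterior Hox, posterior Hox, retinoic acid, p53 and apoptosis, hypoxia and glycolysis, proliferation, unfolded protein and amino acid response, and YAP and TAZ targets. Of the SRF targets of the actin cytoskeleton, 27 of 36 were measured. Each list was tested against the other genes with camera (preset correlation 0.01), adjusted over the 25 lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move 1 way on balance, were alternatives. Members were also counted with p-values adjusted over the list alone. A few genes stand in more than 1 list, such as Ccn1, Ccn2, Foxa2, Krt8 and Snai1.

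Genes named in the text followed a rule: Srf in every sample; for each genotype comparison, the 10 largest rises and 10 largest falls among called genes whose knockout and control arrays do not overlap (for the average, at every stage); the 10 smallest p of the interaction; the 10 largest rises and falls between E9.0 and E8.5 controls; and up to 4 members of each list with the smallest p. Predicted genes and probes without a symbol of their own were passed over. The grouping, comparisons, tests, lists, naming rule and first set of alternatives were chosen before the data were examined. The relation of genotype effects to the control stage change was tested by Pearson and Spearman correlation across genes, with a 2-sided p from the 35 exact splits of 8 arrays.

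The steps were tested on simulated data with known changes in 200 of 11008 genes. With a spread shared by the stages, 95.5%, 82.1% and 92.5% of the 2-fold changes were recovered at E8.5, E8.75 and E9.0, and 61.2%, 43.3% and 52.2% of the 1.5-fold changes. The false share of calls was 3.39%, 3.25% and 7.91%. With each stage's own spread it was 13.3%, 46.2% and 9.39%, and 3.51%, 3.60% and 6.18% with only the groups compared in the fit. At E8.75 with that spread, the 2 fits recovered 83.6% and 59.7% of the 2-fold and 55.2% and 14.9% of the 1.5-fold changes. A simulated shifted list of 20 genes at E8.5 gave a camera p of 1.45e-28, and 0 of 100 unshifted lists had a p under 0.05. The simulated genes varied independently, whereas genes of a measured list correlated within groups by up to 0.905 at E8.5. The simulation thus does not check camera for lists whose genes vary together.

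Those alternatives were the deposited value table, no background correction, normexp with an offset of 50, median scaling, no filter on dim probes, a stricter filter (detection p under 0.01 on at least 12 arrays), every probe by itself, only the groups compared, an intensity trend with a robust prior, array weights, the replicate number as a block, a minimum fold of 1.5, an adjusted p under 0.01, and leaving out each array in turn. A block for the bead chip was planned and not run, because the chip of each array is not given in the sources used here. Alternatives added after seeing the data were covariates for the Xist level, the Actb probe contrast (dim minus bright probes) and the erythroid and yolk sac list means, leaving out the arrays of E8.75 or the genes on the chromosome of Srf, and splitting the E9.0 controls. A list was not tested with its own mean as a covariate, which would fix the outcome. Counts of calls were compared with those of all 35 splits of 8 arrays, or of 100 labellings within stages with seed 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.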

Results

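Gene expression was measured on 24 bead arrays of total RNA from the unsegmented caudal end of mouse embryos. The arrays formed 6 groups of 4: control and Srf knockout embryos at E8.5, E8.75 and E9.0. Srf encodes serum response factor, a transcription factor that drives genes of the actin cytoskeleton and immediate early genes. In the knockouts, the labels give a conditional Srf allele deleted by Cre under the control of the T gene, which is active in the primitive streak and its mesoderm. The controls are named wild type in the sample titles and heterozygous for Srf in the genotype label, so they are called controls here. Of 25697 probes, 14927 passed the filter on dim probes, which left 11008 genes or unnamed probes to test. The median bead intensity per array was 36.8 to 45.9 at E8.5, 145.1 to 173.3 at E8.75 and 36.8 to 38.9 at E9.0. Between 12316 and 13685 probes were detected per array at E8.5, 11329 to 12406 at E8.75 and 12695 to 13625 at E9.0. The number of arrays limits the precision. The median within-group SD over genes was 0.18 on the log2 scale at E8.5, 0.26 at E8.75 and 0.16 at E9.0. At E8.75, stage and brightness cannot be told apart, because all 8 arrays of that stage were bright and no array of another stage was.

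The targeted gene was examined first. Normalized log2 Srf signal (probe ILMN_2988299) averaged 9.26 ± 0.12 in controls and 8.17 ± 0.21 in knockouts at E8.5 (SD, n = 4 per group). At E8.75 the averages were 9.03 ± 0.73 and 8.02 ± 0.36, and at E9.0 they were 9.27 ± 0.11 and 8.45 ± 0.20 (SD, n = 4 per group). The E8.5 controls read 9.11, 9.36, 9.36 and 9.23, and the E8.5 knockouts 8.40, 8.11, 7.92 and 8.26. The E8.75 controls read 8.99, 9.89, 9.13 and 8.10, and the E8.75 knockouts 8.01, 8.51, 7.64 and 7.92. The E9.0 controls read 9.26, 9.13, 9.28 and 9.39, and the E9.0 knockouts 8.46, 8.67, 8.18 and 8.504. The array labelled control E8.75 replicate 4 lay within the knockout range for Srf. Its mean over the SRF targets of the actin cytoskeleton, 8.27, lay above the E8.75 knockouts, which read 7.94 to 8.07. Averaged over the 3 stages, Srf fell by 0.97 ± 0.13 on the log2 scale (SE), with an adjusted p of 0.00011 by limma.

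By stage, the log2 fold change of Srf was -1.09 ± 0.23 at E8.5, -1.005 ± 0.23 at E8.75 and -0.81 ± 0.23 at E9.0, with adjusted p of 0.172, 0.0477 and 0.021 by limma. All 4 knockout arrays lay below all 4 controls at E8.5 and E9.0. Over the alternatives the adjusted p at E8.5 ran from 0.000307 to 0.943, and without the arrays of E8.75, a setting chosen after seeing the data, it was 0.000594. At E8.75 the call was kept without control replicate 4 (0.00123) or knockout replicate 2 (0.0161). It was lost without any of the other arrays, at 0.062, 0.0826 and 0.092 for control replicates 1, 2 and 3 and 0.116, 0.155 and 0.14 for knockout replicates 1, 3 and 4. At E9.0 it was lost without control replicate 4 (0.0612) or knockout replicate 3 (0.0676). Where the probe lies relative to the deleted part of the gene is not given in the sources used here, so its signal may not check the deletion. A dimmer Srf probe, detected on 14 arrays, gave log2 fold changes of -0.44, -0.17 and -0.51 at the 3 stages.

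**Figure D1:**
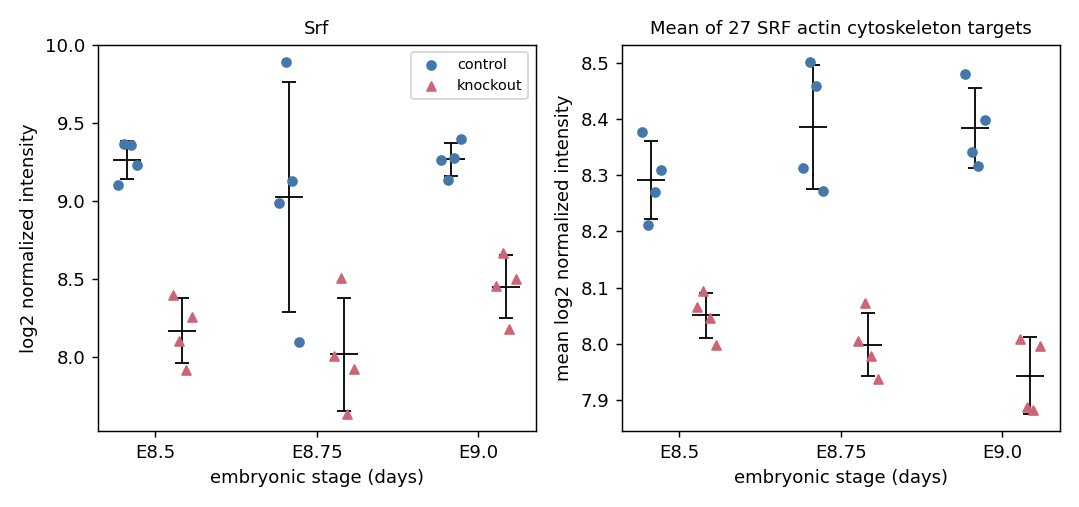
Normalized log2 Srf signal per array (left) and the mean over 27 measured SRF targets of the actin cytoskeleton (right), by stage for control and knockout groups. Points are arrays and bars the mean ± SD of 4 arrays; the control list mean lies at 8.29, 8.39 and 8.38 and the knockout mean at 8.05, 7.998 and 7.94 at E8.5, E8.75 and E9.0.

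The comparison of knockouts with controls at E8.5 asked which genes changed early, while the axis elongates. The list of SRF targets of the actin cytoskeleton fell as a group: 25 of its 27 measured members had negative log2 fold changes, with a median of -0.18 (camera adjusted p = 2.24e-11, and 0.00145 with an estimated correlation). Over the alternatives the median ran from -0.24 with the stricter filter to -0.08 with a normexp offset of 50. The list mean was 8.29 ± 0.07 in controls and 8.05 ± 0.04 in knockouts (SD, n = 4 per group). No member passed on its own over all genes in limma, and 5 fell when adjusted over the list alone. Among its members were Cnn2, which encodes a calponin that binds actin, at -1.03 (adjusted p = 0.172), and Fhl2, a LIM domain cofactor of SRF, at -0.87 (adjusted p = 0.0638). Wdr1, which promotes actin filament disassembly, stood at -0.56 ± 0.10 (SE), adjusted p = 0.0638. The only gene called over all genes tested at E8.5 was Mocs1 (probe ILMN_2679885), an enzyme of molybdenum cofactor synthesis on the same chromosome as Srf, which fell by 0.83 ± 0.12 (SE), adjusted p = 0.00424 by limma, in all 4 knockout arrays. With only the groups compared in the fit, Mocs1 was not called (adjusted p = 0.116) and Srf was the only gene called (0.0381). Over the alternatives the adjusted p of Mocs1 ran from 5.8e-05 to 0.116.

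Among the other lists at E8.5, all 14 measured genes of primitive erythroid cells had negative log2 fold changes, with a median of -0.86 and no member called over all genes or adjusted over the list alone. Their camera adjusted p was 4.55e-05, and adjusted p = 0.701 with an estimated correlation. Without control replicate 3 the median was -0.05 and the camera call was lost. The erythroid list mean was 7.16 ± 1.56 in controls and 6.32 ± 0.89 in knockouts (SD, n = 4 per group). Epithelial genes had a median of 0.11 (camera adjusted p = 0.00364, and adjusted p = 0.404 with an estimated correlation), with no member called over all genes or adjusted over the list alone. That call was lost without control replicate 3 (median 0.036) or knockout replicate 1 (0.093). Of the immediate early SRF targets, 0 of 11 were called over all genes and 1 was higher when adjusted over the list alone. Their median was -0.0029, with a mean of 0.12 (camera adjusted p = 0.674). Egr1, an immediate early transcription factor, had a log2 fold change of 0.80 ± 0.19 (SE), adjusted p = 0.362. Genes of the visceral yolk sac endoderm had a median of 0.05 and those of hypoxia and glycolysis one of -0.0051, each with a camera adjusted p of 0.889. The median of the yolk sac list was -0.40 without knockout replicate 1, with a camera call. Without knockout replicate 4, the medians of the endothelium and hypoxia lists were 0.21 and 0.13, each with a camera call.

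At E8.5, 1 gene of 11008 passed an adjusted p of 0.05 in limma, 0 higher and 1 lower, and 209 had an unadjusted p under 0.05. The 4 knockout and 4 control arrays did not overlap for 223 genes (2.03%), where chance gives 2.86%. The count was 2 without knockout replicate 1 and 2 without knockout replicate 4. Without the arrays of E8.75 it was 7, namely Cnn2, Fhl2, Mocs1, Mpdu1, Srf, Wdr1 and 1 probe without a symbol; Mpdu1 was the 1 gene that was higher. These genes lie outside the naming rule and were named after their values were seen.

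At E8.75 the same comparison gave a group of lower actin genes and a group of higher yolk sac genes. Fhl2 fell by 1.35 ± 0.16 (adjusted p = 0.000103 by limma), Cnn2 fell by 1.37 ± 0.22 (0.00232) and Wdr1 fell by 0.70 ± 0.10 (0.000812). Of the 27 SRF targets of the actin cytoskeleton, 6 fell and 0 rose over all genes, and 10 fell when adjusted over the list alone. The list median was -0.32 (camera adjusted p = 5.61e-11, and 0.00206 with an estimated correlation). Its mean was 8.39 ± 0.11 in controls and 7.998 ± 0.06 in knockouts (SD, n = 4 per group). Mocs1 fell by 1.15 ± 0.12 (adjusted p = 1.5e-05 by limma) and Zfp101, a zinc finger gene, fell by 1.15 ± 0.20 (0.00543). Sik1, a salt inducible kinase, was at least 1.86-fold lower (0.000618). Egr1 rose by 1.39 ± 0.19 (0.000394) and was the only immediate early SRF target of 11 called over all genes. When adjusted over the list alone, 3 of them were higher and 3 lower, with a median of -0.02, a mean of 0.14 and a camera adjusted p of 0.956. Errors are SE, and for each gene named here all 4 knockout arrays lay on 1 side of all 4 controls.

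The larger rises at E8.75 were in genes of the visceral yolk sac endoderm, the extraembryonic layer that makes serum proteins. Apoa1, an apolipoprotein, rose by 4.28 ± 0.65 (adjusted p = 0.00112 by limma), Ttr, the thyroxine carrier transthyretin, by 3.82 ± 0.57 (0.000812) and Spp2, detected on 1 of the 4 controls, by 3.73 ± 0.54 (0.000764). Amn, part of the receptor complex that takes up vitamin B12, rose by 3.27 ± 0.53 (0.00232), and Apom by 2.98 ± 0.50 (0.00276). Slc13a4 and Apoc1, outside the list, rose by 2.79 ± 0.48 (0.00467) and 2.30 ± 0.37 (0.00232). Of the 13 measured members of the list, 7 rose over all genes and 13 when adjusted over the list alone, with a median of 2.51. The camera adjusted p was 6.97e-23, and adjusted p = 0.054 with an estimated correlation. The list mean was 6.11 ± 0.37 in the controls and 8.55 ± 1.13 in the knockouts at E8.75, against 8.85 ± 0.80 and 8.91 ± 1.12 at E8.5 (SD, n = 4 per group). Xist, which is expressed from the inactive X chromosome of females, lay above the Y-linked Kdm5d on 1 of 4 control and 4 of 4 knockout arrays at E8.75. The corresponding numbers were 2 and 1 at E8.5 and 3 and 4 at E9.0.

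Erythroid genes had a median of -1.09 at E8.75, with 0 members called over all genes or adjusted over the list alone (camera adjusted p = 0.00577, and adjusted p = 0.707 with an estimated correlation). Tail bud and primitive streak genes had a median of -0.16, also with 0 members called either way (camera adjusted p = 0.0318, and adjusted p = 0.707 with an estimated correlation). The camera call of the erythroid list was lost without control replicate 1 (median -0.94) or knockout replicate 4 (-0.48). With the Xist level as a covariate, a setting chosen after seeing the data, its median was -0.23 (adjusted p = 0.462). That of the tail bud list was lost without control replicate 1 (-0.13) or 4 (-0.19) and without knockout replicate 3 (-0.13) or 4 (-0.12). The hypoxia list had a median of 0.14 (camera adjusted p = 0.486). The camera adjusted p of the remaining lists at this stage did not reach the threshold of 0.05.

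At E8.75, 58 genes passed in limma, 40 higher and 18 lower, and 1356 had an unadjusted p under 0.05. The arrays of both groups did not overlap for 441 genes (4.01%, where chance gives 2.86%), including 49 of the 58. With only the groups compared in the fit, 5 genes passed: Egr1, Fhl2, Ier3, Mocs1 and Timd2; Ier3 and Timd2 lie outside the naming rule at this stage. The other genes named for E8.75 were not called in that fit. In simulated data with each stage's own spread, 46.2% of the calls at E8.75 were false in the fit of all 24 arrays, against 3.60% in the fit of only the groups compared, which recovered fewer of the 2-fold changes (59.7% against 83.6%). The count was 131 without control replicate 2, 34 without control replicate 3, 23 without knockout replicate 1, 101 without knockout replicate 2, 26 without knockout replicate 3 and 20 without knockout replicate 4. Of the genes named by rank, Mt1 (2.67), Lgals2 (2.34), Pla2g12b (at least 3.39-fold higher), Edn1 (-1.28), Actc1 (at least 1.43-fold lower), Zfp52 (-0.81) and Pdlim7 (-0.76) kept their call in 4, 3, 2, 4, 3, 6 and 5 of the 8 fits without 1 array. The others named by rank kept it in 8 of 8.

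The hypoxia and glycolysis list was higher and the erythroid list lower in the knockouts at E9.0 (camera adjusted p = 2.4e-10 and 1.14e-12, and adjusted p = 0.118 for each with an estimated correlation). Pfkp, a glycolytic phosphofructokinase, rose by 2.78 ± 0.38 (adjusted p = 4.04e-05 by limma; a dimmer probe had 1.28) and Aldoc, a glycolytic aldolase, by 2.42 ± 0.28 (5.91e-06). Chac1, a gene of the amino acid response, rose by 2.72 ± 0.42 (0.000181), Bhlhe40 by 2.56 ± 0.30 (6.1e-06) and Ddit4, an inhibitor of mTOR signalling, by 2.31 ± 0.29 (1.17e-05). Ier3 rose by 2.52 ± 0.42 (0.000327), Nrn1 by 2.45 ± 0.29 (8.04e-06), Chst1 by 2.10 ± 0.21 (1.03e-06) and Ppp1r3c by 2.01 ± 0.27 (3.56e-05). Cav1, which encodes the coat protein of caveolae and was not above background in the controls, was at least 3.24-fold higher (1.93e-10). Alas2, the first enzyme of heme synthesis in red cells, fell by 4.28 ± 0.69 (0.000255), Slc4a1, the anion exchanger of the red cell membrane, fell by 4.30 ± 1.05 (0.00763) and Kel, a red cell surface protein, fell by 3.30 ± 0.40 (8.93e-06). Trim10, Nfe2, Blvrb, Cited4, Ank1 and Car2 fell too, with log2 fold changes of -3.26, -2.90, -2.89, -2.77, -2.60 and -2.60 and adjusted p from 0.000227 to 0.00135. With the Actb probe contrast as a covariate, a setting chosen after seeing the data, Slc4a1, Alas2, Trim10, Nfe2, Blvrb and Cited4 had -2.84, -3.45, -2.69, -2.43, -2.38 and -2.20 and were not called (adjusted p = 0.336, 0.0519, 0.115, 0.0903, 0.0605 and 0.0736). The embryonic globin Hba-x fell by 3.77 ± 1.21 (0.0406), a call kept only without knockout replicate 1 (0.022); without each other array its adjusted p ran from 0.0633 to 0.164. Errors are SE, n = 4 per group, and for each gene named here all 4 knockout arrays lay on 1 side of all 4 controls.

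The SRF targets of the actin cytoskeleton were lower at E9.0 as well. Wdr1 fell by 1.22 ± 0.10 (adjusted p = 5.98e-08 by limma), Fhl2 fell by 1.56 ± 0.16 (1.98e-06) and Tpm1, a tropomyosin, fell by 1.13 ± 0.14 (8.93e-06), and Actc1, cardiac actin, was at least 2.11-fold lower (0.000212). Of 27 measured members, 10 fell and 1, Fhl1, rose over all genes; adjusted over the list alone, 13 fell and 1 rose. The median was -0.42, or -0.36 with members below background at their bound (camera adjusted p = 3.06e-07, and 0.0201 with an estimated correlation). The list mean was 8.38 ± 0.07 in controls and 7.94 ± 0.07 in knockouts (SD, n = 4 per group). The 11 immediate early SRF targets went both ways: Egr1 rose by 1.58 ± 0.19 (8.04e-06) with Ier3, while Ccn1 and Ccn2, secreted matricellular proteins, had log2 fold changes of -0.77 (0.000805) and -0.90 (0.00545) and fell. Over all genes 2 rose and 3 fell, as they did when adjusted over the list alone. Their median was 0.06 and their mean 0.20, whereas camera gave a downward direction (adjusted p = 0.936). The bright Actb probe used here had a log2 fold change of -0.50 at E9.0, and a pair of dimmer Actb probes had 2.84 and 2.73.

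Of the 19 measured genes of hypoxia and glycolysis, all had positive log2 fold changes at E9.0. Over all genes 10 rose and 0 fell, and 14 rose when adjusted over the list alone. Ndrg1 rose by 1.64 ± 0.20 (adjusted p = 8.2e-06 by limma), Egln3, a prolyl hydroxylase that targets HIF, by 1.34 ± 0.17 (1.69e-05) and Vegfa, an angiogenic growth factor, by 1.10 ± 0.17 (0.000131; errors are SE). The list median was 0.63 (camera adjusted p = 2.4e-10, and adjusted p = 0.118 with an estimated correlation; fry adjusted p = 3e-04). The list mean was 9.30 ± 0.07 in controls and 10.05 ± 0.12 in knockouts (SD, n = 4 per group). Of the 14 erythroid genes, 11 fell and 0 rose over all genes, and 14 fell when adjusted over the list alone. Their median was -2.83 (camera adjusted p = 1.14e-12, and adjusted p = 0.118 with an estimated correlation; fry adjusted p = 0.000638). The erythroid list mean was 10.09 ± 0.69 in controls and 7.35 ± 1.05 in knockouts (SD, n = 4 per group). The contrast of dim with bright Actb probes, in log2 units, was -9.09 ± 0.32 in these controls and -5.81 ± 0.86 in these knockouts (SD, n = 4 per group). With that contrast as a covariate, a setting chosen after seeing the data, 297 genes passed at E9.0.

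**Figure D2:**
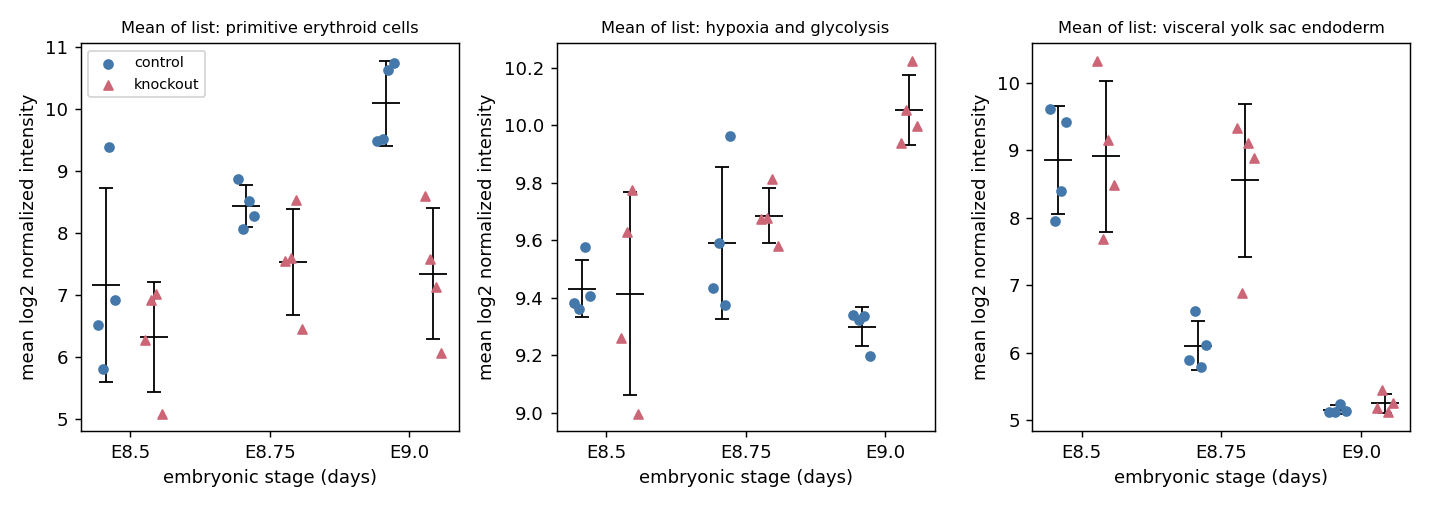
Mean normalized log2 signal per array of the primitive erythroid, hypoxia and glycolysis, and visceral yolk sac endoderm lists (left to right), by stage and genotype. Points are arrays and bars the mean ± SD of 4 arrays; the yolk sac list differs at E8.75 (6.11 in controls, 8.55 in knockouts), and the erythroid list (10.09 and 7.35) and the hypoxia list (9.30 and 10.05) at E9.0.

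The Hox, tail bud, presomitic and somite lists gave no camera call at E9.0, and all but the somite list had called members in both directions. Among 21 posterior Hox genes, 1 rose and 3 fell over all genes, and 2 rose and 3 fell when adjusted over the list alone. Hoxd13 fell by 1.57 ± 0.24 (adjusted p = 0.000158 by limma), Hoxd12 fell by 1.97 (0.00575) and Hoxc11 fell by 0.79 (0.00862), while Hoxa7 rose by 0.72 (0.00851). The median of this list was 0.08 and its mean -0.11 (camera direction down, adjusted p = 0.919). Of 13 anterior Hox genes, Hoxd4 and Hoxd1 rose by 0.66 and 0.47 and Hoxa2 fell by 0.57 (median 0.15, camera adjusted p = 0.789). Of 19 tail bud and primitive streak genes, Wnt5a fell by 0.74 (0.0147) and Cdx4 rose by 0.54 (0.0358; median 0.07, camera adjusted p = 0.747). Of 21 genes of the presomitic mesoderm and segmentation clock, Dusp4 and Notch1 rose by 0.61 and 0.47 and Snai1, a repressor of epithelial genes, fell by 0.75 (median -0.05, camera adjusted p = 0.789). None of the 7 somite genes was called over all genes in limma (median -0.20, camera adjusted p = 0.176). Adjusted over the list alone, the presomitic list had 2 genes higher and 1 lower.

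Lists of adhesion and cell state gave no camera call at E9.0 either. Of 21 genes of focal adhesions, integrins and basement membrane, Dag1, the dystroglycan receptor for laminin, rose by 0.86 (adjusted p = 0.000314 by limma), Itgb5 by 0.68 (0.00126) and Lamc1 by 0.45 (0.0251), and Itgav fell by 0.49 (0.0275). Adjusted over the list alone, 3 were higher and 1 lower; the median was -0.01, the mean 0.03 and the camera direction up (adjusted p = 0.919). Of 18 mesenchymal transition genes, Col1a1 fell by 1.10 (0.0252) and Snai1 fell by 0.75 (0.034), with a median of -0.15 (camera adjusted p = 0.263). Of 19 epithelial genes, Krt19 rose by 0.95 (0.00126), Cldn3 by 0.89 (0.00567) and Grhl3 by 0.69 (0.00565), and 5 were higher when adjusted over the list alone (median 0.13, camera adjusted p = 0.22). Of 9 YAP and TAZ targets, 3 fell: Ankrd1 by at least 1.68-fold (0.00321), with Ccn1 and Ccn2, which the immediate early list also holds. The YAP and TAZ list had a median of -0.21 (camera adjusted p = 0.0584, adjusted p = 0.118 with an estimated correlation, fry adjusted p = 3e-04), with 1 member higher and 4 lower when adjusted over the list alone. It gained a camera call without control replicate 2 (median -0.22, adjusted p = 0.0451) or 3 (-0.32, 0.031), without knockout replicate 1 (-0.32, 0.0452) or 2 (-0.22, 0.0319), and with every probe tested by itself (-0.36, 0.0141).

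The remaining lists at E9.0 gave no camera call in the fit of all 24 arrays. Neural tube genes had 2 of 14 higher, Hes5 by 1.43 (adjusted p = 0.00722 by limma) and Irx5 by 0.81 (0.0393), and 4 when adjusted over the list alone (median 0.23, camera adjusted p = 0.122, fry adjusted p = 0.045). Neural crest and surface ectoderm genes had 3 of 8 higher, Tfap2c and Wnt6 by 0.90 each and Wnt10a by 0.54 (median 0.23, camera adjusted p = 0.22, fry adjusted p = 0.0374). Gut endoderm genes had 3 of 13 lower, among them the pioneer factor Foxa1 at -1.49 (0.00221) and Cpn1 at -0.66 (0.0163; median -0.25, camera adjusted p = 0.101). Notochord and node genes had 3 of 10 lower, Noto at -0.65, Lefty1 at -0.58 and Foxa2 at -0.52 (median -0.0085, camera adjusted p = 0.389). Endothelial genes had 2 of 17 lower, Emcn at -2.28 (0.000181) and Robo4 at -0.84 (0.00377; median -0.25, camera adjusted p = 0.101). Without knockout replicate 1 the neural tube, gut endoderm and endothelium lists had medians of 0.25, -0.31 and -0.39 with a camera call (adjusted p = 0.0452, 0.0452 and 0.0391), and without knockout replicate 2 medians of 0.33, -0.35 and -0.37 with one (0.038, 0.0135 and 0.00192). Of 17 lateral plate and allantois genes, Osr1 rose by 0.65 and Vcam1 was at least 1.20-fold lower (median -0.14, camera adjusted p = 0.554). None of 7 cardiomyocyte genes was called over all genes in limma, and 1 was higher and 1 lower when adjusted over the list alone (median -0.03, camera adjusted p = 0.789).

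Of 10 retinoic acid genes at E9.0, Crabp1 rose by 0.65 and Stra6 fell by 0.77 (median -0.09, camera adjusted p = 0.789). Of 15 p53 targets and apoptosis genes, Bbc3, a mediator of cell death, rose by 1.15 (adjusted p = 0.00104 by limma; median 0.0086, camera adjusted p = 0.953). Of 19 proliferation genes, Mcm6 fell by 0.66 and Ccne1 fell by 0.54 (median -0.01, camera adjusted p = 0.343). Of 16 genes of the unfolded protein and amino acid response, Chac1 rose with Vldlr, which rose by 1.43 (0.00111); the median was -0.05, the mean 0.22 and the camera direction up (adjusted p = 0.747). Of the 58 list members named for E9.0, 39 kept their call in each of the 8 fits without 1 array. Among the other 19, Stra6 and Ccne1 kept it in 7 of 8, Wnt5a, Cpn1, Hoxa2 and Mcm6 in 6, Lamc1, Hoxd4, Hoxd1 and Osr1 in 4, Cdx4 and Snai1 in 3, Itgav, Col1a1, Irx5, Lefty1 and Wnt10a in 2, and Noto and Foxa2 in 1. The 13 yolk sac endoderm genes had 0 members called over all genes or adjusted over the list alone at E9.0, with a median of -0.0045, a mean of 0.09 and a camera direction up (adjusted p = 0.919). Where no count adjusted over the list alone is given for a list at E9.0, it was the same as that over all genes.

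At E9.0, 1454 genes (13.2%) passed in limma, 805 higher and 649 lower, and 2971 had an unadjusted p under 0.05. The groups did not overlap for 2802 genes (25.5%, where chance gives 2.86%), including 1308 of the 1454. Scaling each array to the same median shifted the median of all genes by 0.10 and gave 996 calls, 608 higher and 388 lower. With only the groups compared in the fit the count was 2383, and with the erythroid list mean as a covariate it was 508.

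**Figure D3:**
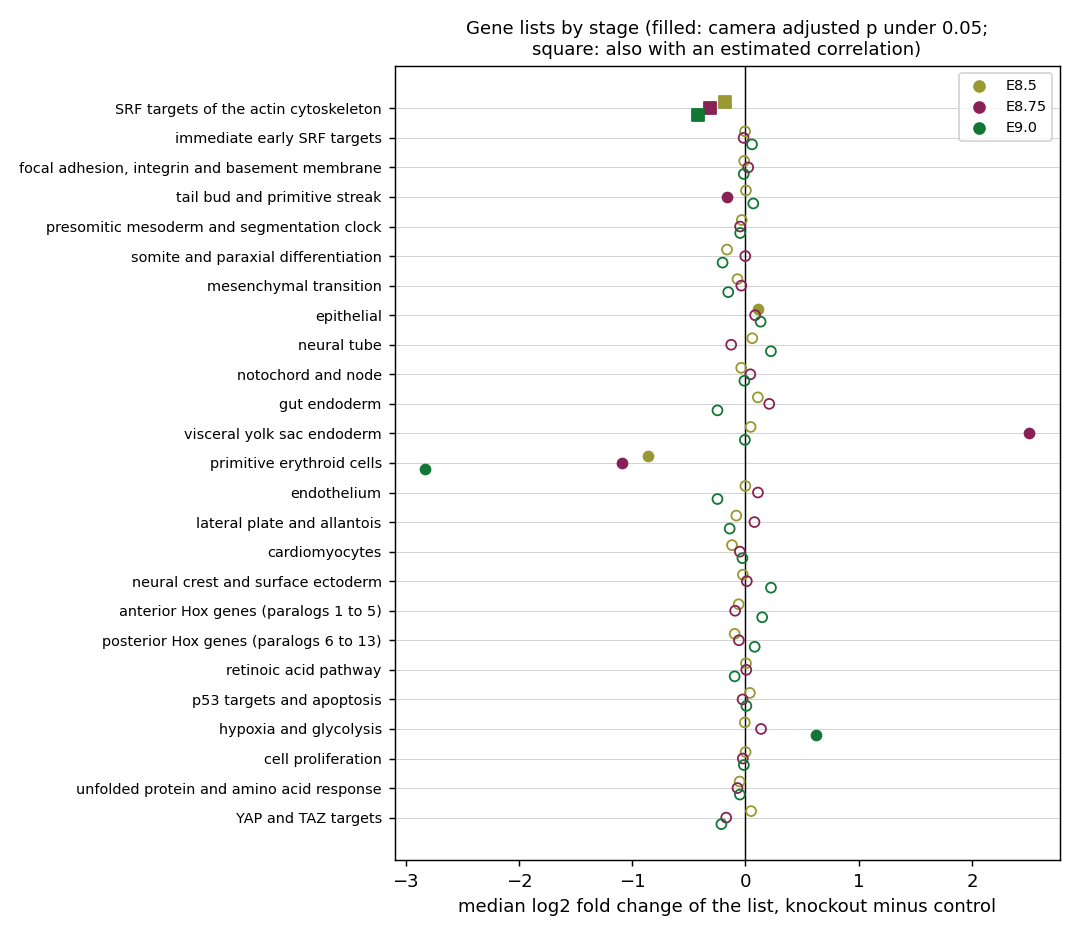
Median log2 fold change (knockout minus control) of each gene list (1 line each) at E8.5, E8.75 and E9.0, from 4 arrays per group; filled points passed camera and squares passed with an estimated correlation too. The SRF targets of the actin cytoskeleton lie at -0.18, -0.32 and -0.42, the yolk sac endoderm list at 0.05, 2.51 and -0.0045, the erythroid list at -0.86, -1.09 and -2.83 and the hypoxia list at -0.0051, 0.14 and 0.63.

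The average over the 3 stages asked which changes were common to them. Fhl2 fell by 1.26 ± 0.09 (adjusted p = 5.34e-09 by limma), Cnn2 fell by 1.22 ± 0.13 (2.18e-06), Wdr1 fell by 0.82 ± 0.06 (3.42e-09), Tpm1 fell by 0.76 ± 0.08 (2.18e-06) and Pdlim7, a LIM protein of actin bundles, fell by 0.60 ± 0.08 (0.00011). Mocs1 fell by 1.16 ± 0.07 (1.47e-10) and Zfp101 fell by 1.00 ± 0.12 (1.06e-05). Egr1 rose by 1.26 ± 0.11 (8.88e-08) and Vars2, a mitochondrial valine tRNA ligase on the chromosome of Srf, by 0.66 ± 0.12 (0.00109). For each of these, errors being SE, the knockout and control arrays did not overlap at any stage. In all, 2 genes were called higher and 10 lower in this way; 3 of the lower ones have no symbol of their own and were passed over by the naming rule. Of the 27 SRF targets of the actin cytoskeleton, 13 fell and 0 rose over all genes, and 16 fell and 1 rose when adjusted over the list alone (median -0.28, camera adjusted p = 1.19e-12, and 0.000786 with an estimated correlation).

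Other lists called by camera in the average lost the call with an estimated correlation. They were the erythroid (median -1.59, 11 fell over all genes, 14 when adjusted over the list alone, adjusted p = 0.152 with an estimated correlation) and hypoxia lists (0.27, 7 rose, 8 when adjusted over the list alone, adjusted p = 0.389 with an estimated correlation). The yolk sac (0.89, 6 rose, 8 when adjusted over the list alone, adjusted p = 0.471), epithelial (0.10, 3 rose, 3 when adjusted over the list alone, adjusted p = 0.389) and YAP and TAZ lists (-0.08, 3 fell, 3 when adjusted over the list alone, adjusted p = 0.152) did so too, each p being the one with an estimated correlation. The epithelial call was also lost without control E8.5 replicate 3 (median 0.068). The YAP and TAZ call was lost without each of 6 arrays: control E8.5 replicate 3, knockout E8.5 replicate 1, control E8.75 replicate 1, knockout E8.75 replicate 4, control E9.0 replicate 1 and knockout E9.0 replicate 3, with medians from -0.085 to -0.072. In the genotype comparisons, the SRF targets of the actin cytoskeleton were the only list whose call held with an estimated correlation, and it held at each stage and in the average. In all, 896 genes (8.14%) passed in limma for the average, 513 higher and 383 lower, with 2631 at an unadjusted p under 0.05. The higher share was 57.3%, and 67.4% with each array scaled to the same median (715 calls, 482 higher and 233 lower). The count was 457 with the Xist level, 232 with the Actb probe contrast, 162 with the erythroid mean and 513 with the yolk sac mean as a covariate.

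The stages share no arrays, but their calls rest on 1 shared estimate of the spread, which favours genes of low spread at each stage. The number of genes this alone would share was not estimated. Between E8.75 and E9.0, 13 genes were lower at both stages. They were Actc1, Cnn2, D16Ertd472e, Edn1, Fhl2, Mocs1, Pdlim7, Polh, Sik1, Srf, Tpm1, Wdr1 and Zfp101. There were 7 higher at both stages, among them Egr1, Nrn1, Atraid, Atp6v1g1, Pxmp4 and S100a1. Independent lists would share 1.06 lower and 2.93 higher genes, a reference that leaves out the shared estimate of the spread. Mocs1, the 1 gene called at E8.5, was lower at all 3 stages. Members of these overlaps outside the naming rule were named after their values were seen.

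The interaction test asked whether the knockout effect differed between stages. Differences are given as the later effect minus the earlier, ± SE, with the adjusted p of limma's moderated F test. Dbp, a clock output gene (1.57 ± 0.20, 0.000325), Aacs (1.38 ± 0.20, 0.000838), Chst1 (2.05 ± 0.30, 0.0022) and Renbp (1.35 ± 0.20, 0.00249) had a higher effect at E9.0 than at E8.5. Ambp, a serum protein precursor (-2.33 ± 0.32, 0.00111), had a lower effect at E9.0 than at E8.75, and Scd1, a fatty acid desaturase (1.38 ± 0.25, 0.01), a higher one. Mrc1, a macrophage mannose receptor, had a higher effect at E8.75 than at E8.5 (1.17 ± 0.18, 0.00237), with signal above background on 1 of the 4 E8.75 controls. Cav1 (1.96e-07), Htra3 (0.0031) and Atg9b (0.01) passed too, but their differences are not sized because some groups compared were not above background. Cav1 lacked signal in the E9.0 controls and E8.5 knockouts, and Htra3 and Atg9b in both groups at E8.5 and E8.75. At E9.0 the log2 fold changes of Htra3 and Atg9b were -1.09 and 0.80. In all, 104 genes passed, with 1446 at an unadjusted p under 0.05. Between pairs of stages, 2 genes differed for E8.75 minus E8.5, 93 for E9.0 minus E8.5 and 109 for E9.0 minus E8.75. The interaction count was 35 without control E9.0 replicate 4, 52, 48, 49 and 58 without control E9.0 replicate 3 and knockout E9.0 replicates 2, 3 and 4, 158 without control E8.5 replicate 1 and 201 without the array labelled control E8.75 replicate 4.

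The control arrays gave the change with stage as background to the genotype effects. From E8.5 to E9.0, the posterior Hox genes Hoxc10 and Hoxd10 rose by 5.89 ± 0.37 (adjusted p = 8.58e-11 by limma) and 5.05 ± 0.38 (1.97e-09), and Hoxd13 by 2.97 ± 0.24 (8.45e-09). Of 21 posterior Hox genes, 12 rose and 2 fell over all genes, 13 and 2 when adjusted over the list alone, with a median of 0.85 (camera adjusted p = 3.53e-06, and 0.0498 with an estimated correlation). The embryonic globin Hbb-y rose by 5.64 ± 1.29 (0.00227), Alas2 by 4.23 ± 0.69 (9.85e-05) and Hba-x by 4.37 ± 1.21, the last in 7 of 8 fits without 1 array. Of 14 erythroid genes, 13 rose and 0 fell over all genes and when adjusted over the list alone (median 2.89, camera adjusted p = 1.04e-08, and adjusted p = 0.251 with an estimated correlation). Spink1 fell by 7.31 ± 0.53 (1.22e-09), Apoa1 fell by 6.39 ± 0.65 and Nr6a1, an orphan nuclear receptor, fell by 4.06 ± 0.28 (7.16e-10), and Ttr was at least 133-fold lower (3.68e-09). Cdx1, a caudal homeobox gene, fell by 3.70 ± 0.38 (2.45e-07). All 13 yolk sac endoderm genes fell (median -3.45, camera adjusted p = 5.13e-13, and adjusted p = 0.205 with an estimated correlation). Errors are SE, and for the genes named by rank the 4 arrays of each stage did not overlap.

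Further lists were called by camera between the E9.0 and E8.5 controls. The epithelial list had 2 members higher and 8 lower (median -0.26, adjusted p = 0.0366), among them Krt8 at -1.69, and the gut endoderm list 1 higher and 5 lower (-0.45, 0.00353), and both lost the call with an estimated correlation (adjusted p = 0.287 and 0.251). The anterior Hox list had 5 higher and 1 lower (0.21, 0.0203) and the YAP and TAZ list 6 higher and 0 lower (0.60, 0.0126), with adjusted p = 0.287 and 0.0709 with an estimated correlation. The epithelial call was also lost without control E8.5 replicate 1 (-0.24), 2 (-0.13) or 4 (-0.23), or control E9.0 replicate 3 (-0.21). Tail bud genes went both ways without a camera call (adjusted p = 0.296): Wnt5a rose by 1.86 and Fgf17 by 1.13, and Cdx4 fell by 0.79. In limma, 2911 genes passed between E9.0 and E8.5, 1342 higher and 1569 lower, and the stages did not overlap for 34.7% of genes, where chance gives 2.86%.

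The comparisons with the E8.75 controls carry the difference in brightness of that stage. Between E8.75 and E8.5, 4027 genes passed in limma, 2220 higher and 1807 lower, and all 13 yolk sac endoderm genes fell (median -2.68, camera adjusted p = 1.91e-08, and adjusted p = 0.633 with an estimated correlation). Between E9.0 and E8.75, 4501 passed, 1874 higher and 2627 lower. With each array scaled to the same median the split turned, to 1613 higher and 4108 lower of 5721 (28.2% higher, against 55.1%) and to 4511 higher and 1871 lower of 6382 (70.7% higher, against 41.6%). The median of all genes moved to -0.24 and 0.25 under that scaling. Probes of the same gene changed differently with stage for 1207 and 1229 of 2743 genes with several probes in these comparisons, against 598 between E9.0 and E8.5 and 0, 6 and 83 in the genotype comparisons at E8.5, E8.75 and E9.0.

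Correlations across genes asked whether knockouts resembled younger or older controls, using contrasts that share no arrays. Across 11008 genes, the genotype effect at E9.0 and the control change from E8.5 to E8.75 had a Pearson r of -0.0045 (exact permutation p = 0.886) and a Spearman rho of 0.029 (exact permutation p = 0.543), both tests over the 35 splits of 8 arrays and 2-sided. The genotype effect at E8.5 and the control change from E8.75 to E9.0 had r = -0.21 (exact permutation p = 0.2) and rho = -0.17 (exact permutation p = 0.143). In the family of 8 such relations, the Benjamini-Hochberg adjusted values were 0.886, 0.62, 0.4 and 0.4. Genes are not independent replicates, and neither relation passed. Both control changes include the bright E8.75 controls. Probes of the same gene changed differently along them for 44.0% and 44.8% of genes with several probes. These relations thus cannot part embryo age from brightness, and no conclusion on age is drawn from them. In a comparison added after seeing the data, the genotype effect at E9.0 and the control change from E8.5 to E9.0 had a mean r of -0.27 (-0.34 to -0.22) and a mean rho of -0.18 over 6 ways of splitting the E9.0 controls. With the same controls in both contrasts r was -0.33, and the covariance was -0.0654 against -0.0554 with the controls split.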

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

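The tests of carried-over yolk sac and of embryo sex for the yolk sac genes, of age for the hypoxia genes and of alleles linked to Srf were chosen after their results were seen, as were the joint view of erythroid and hypoxia genes and the covariates.

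Yolk sac endoderm genes were higher in the knockouts at E8.75, with a list median of 2.51. Unequal embryo sex is argued against as the whole cause, since the median was 2.52 with the Xist level as a covariate. The SE of the list mean's effect in that fit was 0.66. At E8.75 Xist lay above Kdm5d on 1 of 4 controls and 4 of 4 knockouts, so the slope on Xist rests largely on the other stages. Apoa1, Ttr, Amn and Apom lost their calls with this covariate. Carried-over yolk sac endoderm stays open: across E8.5 arrays of the same group the list's genes varied together, with a mean pairwise correlation of 0.905. The other 24 lists had -0.036 to 0.709, the highest being the erythroid list, and the hypoxia list had 0.546. The yolk sac signal thus differed between arrays of 1 group. That does not part carried-over tissue from a spread of ages or from a change in the endoderm itself. A younger age of the knockouts cannot be told apart from this, because the slope of the genotype effect on the control change from E8.5 to E9.0 was -0.194, with a spread of 0.098 over splits, close to the bound set for excluding it and far from the list's own ratio of -0.726. No other biological explanation was tested.

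Hypoxia genes were higher (median 0.63) and erythroid genes lower (-2.83) in the E9.0 knockouts. Each SE in this paragraph belongs to the effect on the list mean, not to the median beside it. For the hypoxia genes, an age of E8.5 is argued against, since the E9.0 knockouts lay a median of 0.58 (SE 0.079) above the E8.5 controls. The camera p of 9.78e-06 became 0.106 with an estimated correlation, however. An age nearer to E8.75 stays open. The hypoxia list mean of the E8.75 controls was 9.59 (9.38 to 9.96), and that of the E9.0 knockouts ran from 9.94 to 10.22. Unequal sex is argued against as a whole cause too (median 0.63, SE 0.14, with the Xist level). The median was 0.79 (SE 0.18) with the erythroid mean and 0.71 (SE 0.20) with the Actb probe contrast as a covariate. Neither covariate overlapped between genotypes at E9.0. The erythroid mean was 9.48 to 10.74 in controls and 6.07 to 8.60 in knockouts, and the Actb contrast -9.55 to -8.84 and -6.99 to -5.01. Both adjustments thus extrapolate with a slope over all groups, so erythroid share and RNA quality stay open. For the erythroid genes, sex is argued against (-2.58, SE 0.69, with the Xist level). The slope on the control change from E8.5 to E9.0 was -0.178 (the list's own ratio was -0.979), close to the bound of -0.2 set for excluding age. The spread of 0.028 over splits belongs to another axis, the control change from E8.5 to E8.75. Age as the whole cause is argued against only by the posterior Hox list mean, looked up after the results were seen. It was 8.05 ± 0.09 in the E9.0 knockouts and 8.16 ± 0.15 in the E9.0 controls (SD, n = 4 per group). The E8.75 controls had 7.44 ± 0.09 and the E8.5 controls 7.01 ± 0.16. Single members differ from this mean. At E9.0 Hoxd13, which rose with stage in the controls, Hoxd12 and Hoxc11 had log2 fold changes of -1.57, -1.97 and -0.79, and Hoxa7 had 0.72. A smaller contribution of age stays open. Erythroid signal also varied within groups: the list mean of the E8.5 controls ran from 5.80 to 9.39. Whether differing blood content of the dissected tissue explains the erythroid fall was not tested. No other biological explanation of the 2 lists was tested.

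Changed genes lay often on the chromosome of Srf: 1.82% of its 494 tested genes were called at E8.75 against 0.477% of the others, and 16.8% against 13.1% at E9.0. Alleles of another strain linked to the Srf locus may contribute, since 4 of the 200 genes nearest to Srf had a p under 0.01 at E8.5, where the highest of 41 other windows had 3 and their median was 0. At E9.0 the window near Srf had 46, against a highest other of 40. At E8.75 it did not stand apart, with 14 against a highest other of 16, and 4 of the 41 windows had as many. Mocs1, 33 measured genes from Srf, is among the genes this covers, and without the chromosome of Srf the called genes numbered 0 at E8.5, 43 at E8.75 and 1368 at E9.0. An effect of SRF itself on these genes stays open and was not tested.

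Relabelling the arrays showed where chance can be excluded. At E8.5 it cannot: 4 of 35 splits gave as many genes as the real 1, and the highest other gave 23. At E8.75 the real split gave the most calls, with 1 of 35 (58 against 37). That is the smallest share that 35 splits can give, and another split gave 37 calls. Chance is thus not excluded for the 58 calls. At E9.0 chance can be excluded for the count, with 1 of 35 (1454 against 19). The control comparisons gave 1 of 35 each, with 4027 against 690 between E8.75 and E8.5, 4501 against 489 between E9.0 and E8.75, and 2911 against 56 between E9.0 and E8.5. Chance can be excluded for the average, with 1 of 100 labellings (896 against 298). For the interaction, 3 of 100 labellings gave as many genes (104 against 531). Relabelling within stages also breaks the genotype effect that the stages share, so it cannot test a difference between stages. No conclusion on chance is drawn for the interaction. The value of 531 is several times the real count. A labelling that keeps or flips the genotypes of E9.0 and mixes those of another stage can turn the E9.0 effect into a difference between stages. Which labelling gave 531 was not examined, so no structure of the samples is read from it, and none was tested.

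Single arrays stood far from the other 3 of their group in 9 of 174 groups tested, where chance gives about 1 in 20, or 8.7. Knockout E8.5 replicate 4 stood apart in the mean of the focal adhesion list (7.98, others 8.21 to 8.24), the tail bud list (9.68, others 9.23 to 9.27) and the endothelium list (6.81, others 7.54 to 7.68), and in detected probes (12316, others 13495 to 13535). Control E8.5 replicate 3 had an epithelial mean of 6.99 (others 7.29 to 7.31). Control E8.5 replicate 2 had an unfolded protein response mean of 7.93 (others 8.03 to 8.04). Control E8.75 replicate 2 had a gut endoderm mean of 7.62 (others 7.21 to 7.25). Control E9.0 replicate 3 had a yolk sac mean of 5.25 (others 5.12 to 5.14). Control E9.0 replicate 4 had a hypoxia mean of 9.20 (others 9.32 to 9.34).

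Knockout effects differed between stages by limma's test for 10 named genes. From E8.5 to E9.0 the effect changed by 1.57 for Dbp, 1.38 for Aacs, 2.05 for Chst1 and 1.35 for Renbp. From E8.75 to E9.0 it changed by -2.33 for Ambp and 1.38 for Scd1, and from E8.5 to E8.75 by 1.17 for Mrc1. The fitted values of 2.02 for Cav1 (E8.5 to E9.0), -1.05 for Htra3 and 1.00 for Atg9b (E8.75 to E9.0) include groups that were not above background, so they do not measure the size of a difference. By camera, the median differences of lists were 2.46 for yolk sac endoderm from E8.5 to E8.75. From E8.5 to E9.0 they were -0.22 for SRF targets of the actin cytoskeleton, -0.42 for gut endoderm, -1.72 for erythroid genes, 0.56 for hypoxia and -0.38 for YAP and TAZ targets. From E8.75 to E9.0 they were 0.29 for tail bud, 0.41 for neural tube, -0.37 for gut endoderm, -2.53 for yolk sac endoderm, -1.81 for erythroid genes, -0.31 for endothelium and 0.58 for hypoxia. None of these list differences passed with an estimated correlation.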

How the results depend on the processing

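The settings with the Xist level, the Actb probe contrast or a list mean as a covariate, without the arrays of E8.75 and without genes on the chromosome of Srf were added after the data were seen. For genes the text names, 13411 of 14146 values under an alternative kept their side of the threshold, 558 lost a call, 176 gained one and 1 turned. For lists the numbers were 4493 of 4692, 82, 110 and 7. Direction was compared only where the main fit or the alternative gave a call. A change of sign without a call is therefore not counted as turned. The main fit called 248 of 538 gene results and 30 of 175 list results. The SRF targets of the actin cytoskeleton kept their call and direction at each stage under every setting run, while the size of the median moved: -0.24 to -0.08 at E8.5, -0.42 to -0.17 at E8.75, -0.49 to -0.28 at E9.0 and -0.40 to -0.20 in the average. At E8.5 it was -0.08 with the deposited table, a normexp offset of 50, median scaling or every probe by itself, -0.09 without background correction and -0.10 with no filter on dim probes. The yolk sac median at E8.75 ran from 1.39 with every probe by itself to 3.36 without knockout replicate 2, the erythroid median at E9.0 from -3.13 to -1.63 and the hypoxia median at E9.0 from 0.47 to 0.79. Signal over background limits dim probes, and at E8.75 the spread is larger than the pooled estimate. Unless a reason is given, the cause of a move was not tested.

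At E8.5 the count of 1 was 2 with the deposited value table, no background correction, normexp with offset 50, no filter on dim probes, or an intensity trend with a robust prior, always Mocs1 and Wdr1. It was 1 with only the groups compared too, but that gene was Srf, with Mocs1 at an adjusted p of 0.116. It was 9 with array weights, 7 without the arrays of E8.75 and 0 without genes on the chromosome of Srf, and 1 to 2 without 1 array. At E8.75 the count of 58 was 34 with the deposited table, 34 without background correction, 35 with normexp offset 50, 122 with median scaling, 5 with only the groups compared, 512 with array weights and 17 at an adjusted p under 0.01. It was 7 with the Xist level, 27 with the erythroid mean and 4 with the yolk sac mean as a covariate, and 20 (without knockout replicate 4) to 131 (without control replicate 2) without 1 array. At E9.0 the count of 1454 was 2383 with only the groups compared, 3012 with array weights, 776 at 1.5-fold, 723 at an adjusted p under 0.01, 297 with the Actb probe contrast and 508 with the erythroid mean. Stricter thresholds lower a count by construction.

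For the average, the count of 896 was 1868 with array weights, 120 at 1.5-fold, 277 at an adjusted p under 0.01, 457 with the Xist level, 232 with the Actb probe contrast, 162 with the erythroid mean and 513 with the yolk sac mean. For the interaction, the count of 104 was 34 with median scaling, 1046 with array weights, 8 at an adjusted p under 0.01, 13 with the Actb probe contrast, 55 with the erythroid mean, 60 with the yolk sac mean, and 35 to 201 without 1 array. Between E8.75 and E8.5 controls, the count of 4027 was 2536 with only the groups compared, 2187 at 1.5-fold, 2640 at an adjusted p under 0.01 and 1937 with the Actb probe contrast. Between E9.0 and E8.75 controls, 4501 became 2535 at 1.5-fold and 767 with the Actb probe contrast. Between E9.0 and E8.5 controls, 2911 became 4714 with array weights, 1605 at 1.5-fold and 1694 at an adjusted p under 0.01.

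List medians that turned with a call in 1 of the fits were endothelium at E8.5 (0.16 with array weights, and -0.087 to 0.21 without 1 array), hypoxia at E8.5 (0.12 with array weights, and -0.095 to 0.13 without 1 array) and yolk sac endoderm at E8.5 (-0.40 to 0.49 without 1 array). Tail bud genes at E8.75 had 0.0043 with the yolk sac mean, endothelium in the average 0.22 with the erythroid mean, and Pla2g12b at E8.75 -0.19 with the yolk sac mean. Among erythroid genes at E9.0, Trim10 (-0.70, adjusted p = 0.422), Blvrb (-0.98, 0.124) and Ank1 (-1.19, 0.118) also lost their call with the erythroid mean, which removes by construction what they share with that list. At E8.75 Apoa1, Ttr, Amn and Apom lost theirs with the Xist level (adjusted p = 0.063, 0.0612, 0.137 and 0.145). The lowest rises of these genes over all alternatives run for them were 3.66, 3.39, 2.48 and 2.28. Lists without a call that gained one in some settings included posterior Hox and cardiomyocytes at E8.5 (-0.20 with the stricter filter and -0.23 with array weights). At E8.75 they included neural tube (-0.28 with median scaling) and hypoxia (0.17 with array weights). Gut endoderm and YAP and TAZ targets gained one there too (0.21 and -0.17 with only the groups compared). Endothelium did so at E9.0 (-0.17 with median scaling). Not every gain is given, in particular for fits without 1 array. The erythroid list at E8.75 (-1.09) had -0.23 with the Xist level (adjusted p = 0.462), -0.75 with the yolk sac mean (0.304) and -1.02 with array weights (0.262), each without a call, and at E8.5 it had -0.37 with array weights (0.0543). The tail bud list at E8.75 lost its call with median scaling (0.113), no filter on dim probes (0.0549) and array weights (0.773). The YAP and TAZ list in the average, called at -0.075, had 0.012 and no call with no filter on dim probes (adjusted p = 0.563). The endothelium list between E9.0 and E8.75 controls, at 0.024 without a call, had -0.83 and a call with the Actb probe contrast. With an estimated correlation, the yolk sac list at E8.75 (2.51), the erythroid list at E9.0 (-2.83) and the hypoxia list at E9.0 (0.63) kept their medians and lost the call.

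The arrays of different groups share only replicate numbers. In 12 pairs of control and knockout arrays of a stage with the same number, deviations from the group means correlated by -0.26 to 0.40, 2 of them over 0.1, and in 2 pairs the arrays correlated best with their own number. With the replicate number as a block (replicate block), the interaction gave 57 calls; the other counts were 1, 49, 1393 and 764 for the genotype effects at E8.5, E8.75, E9.0 and in the average, and 3898, 4363 and 2780 for the control changes. The bead chip block was not run, since the chips are not given in the sources used here.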

Other observations

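The genes near Srf and the control list members below were looked up after their values were seen, outside the naming rule or in a comparison the text had not described.

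Several changed genes neighbour Srf on its chromosome. Averaged over the stages, the translesion polymerase gene Polh, 9 measured genes from Srf, fell by 0.68 ± 0.09 (limma adjusted p = 4.54e-05), and the immune genes H2-T23 and H2-Bl rose by 0.87 ± 0.17 (0.00319) and 0.83 ± 0.20 (0.0118). Guca1a, 18 genes away, rose by 0.56 ± 0.10 (0.000979) and Dennd1c, 75 genes away, fell by 0.75 ± 0.13 (0.00106). Vegfa of the hypoxia list and Trim10 and Rhag of the red cell genes lie 14, 42 and 33 genes away. Ier3 of the immediate early list and Apom of the yolk sac list lie 60 and 77 genes away. They rose by 1.62 ± 0.24 (0.000231) and 1.06 ± 0.29 (0.0235). Errors are SE over 12 knockout and 12 control arrays.

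In the control arrays between E8.5 and E9.0, Hoxa10 was at least 4.13-fold higher, Itgb1, an integrin subunit, rose by 1.27, Tpm1 by 1.12, Nrarp by 1.55, Tcf15, a paraxial mesoderm factor, by 1.13 and Igfbp3 by 1.62. Hes5 fell by 1.71 and Etv2, a factor of early blood and endothelial cells, fell by 1.89. The contrast of dim with bright Actb probes averaged -7.21 ± 1.20 in controls and -6.08 ± 1.76 in knockouts at E8.5, and -3.14 ± 0.97 and -3.51 ± 1.15 at E8.75 (SD, n = 4 per group).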
